A study of Arabidopsis thaliana with 4 samples.

How the data were processed

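RNA was extracted from rosette leaves of WT plants and of plants expressing ERF4 from the 35S promoter, and libraries were sequenced on an Illumina instrument, per the labels' protocols and the series' design text. There were 4 libraries, 2 per genotype, from plants aged 28 days. The authors deposited 1 table of TPM per gene and library. Per the submitters' processing notes fastp, HISAT and RSEM were used, with no versions or roles given. The genome build, the gene annotation and any filter are not given in the sources used here. The 2 columns that hold the authors' mean TPM of each genotype were used in no test. The second WT library is replicate 2 by its title, although its column carries another number, and the label that ties the column to the sample was followed. None of the columns mapped to a sample is numbered 2 for WT.

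TPM divides each library by its own total, so every library has the same sum over the 33059 features and keeps no read number. Depth per library is therefore unknown, and no counting interval can be given. A large change in a few abundant transcripts moves all others in such values. The 10 most abundant features held 10.2% and 7.71% of TPM in WT replicates 1 and 2 and 8.11% and 10.2% in OE replicates 1 and 2. The table lists 226 features with assembled rather than annotated names, 133 chloroplast features and 152 mitochondrial features. The other 32548 matched a locus tag of the RefSeq gene table for Arabidopsis, assembly TAIR10.1, of which 10804 have a symbol other than the locus. Since the authors' build is not named, that table served only for names and gene type, and no coordinates are given.

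Features with a mean of at least 1 TPM over the 4 libraries were tested, 20010 in all. Values were log2(TPM + 1), so a fold change on this scale understates the change of low genes. The comparison of OE with WT used limma 3.58.1 in R 4.3.3 with a variance trend, genotype as the only term and two-sided moderated tests, at a Benjamini-Hochberg adjusted p of 0.05 over all tested features. Residual degrees of freedom were 2 and the prior added 8.73, so the estimated spread of a gene comes largely from other genes. Python 3.11.15 and matplotlib 3.10.9 drew the figures. A feature listed at 0 can be a failed estimate, and no fold is given against a group at 0.

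Before the data were examined 31 gene lists with 448 members were written from general knowledge of Arabidopsis, among them 6 lists of markers of other cell types and organs. Members were matched by locus, and 4 were left out because their symbol differed from that of the reference. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. Members were also counted with an adjustment over the list alone.

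The genes named were fixed by a rule before the data were examined. ERF4, CAT3 and PDF1.2 were always named. Then came up to 10 genes per direction with the largest log2 fold change among those past the threshold that had a mean of at least 5 TPM, a symbol, and both OE libraries on the same side of both WT libraries. Where fewer than 10 passed, up to 5 with the smallest p were added per direction and given as not passing. In each list up to 4 called members were named, or the 2 with the smallest p if none was called. Genes named outside this rule are said to have been chosen after their values were seen.

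The test was checked on simulated data with the means and spread of the 20010 features. It called 0% of 50 genes changed 2-fold, 48% of 50 changed 4-fold, 96% of 50 changed 8-fold and 100% of 50 changed 16-fold, with 4 false calls among 126. Of 1000 random lists of 13 genes, 1.9% had a camera p under 0.05 in simulated data and 5% in the real values. Random genes are not picked from a shared pathway, so this does not check lists of genes that vary together.

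Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, quantile normalization, median-ratio scaling, removal of organelle genes, a robust variance prior, no variance trend, the replicate number as a block, leaving out each library in turn, and the other set tests. Those chosen after seeing the data were removal of the ribosomal RNA features, protein-coding loci alone, and features above 0 in both genotypes. Enrichment of annotation terms had been planned, but the table as used here carries no terms, so neither it nor its alternatives were run. Agreement of libraries was the Pearson correlation across tested features.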

Results

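Transcript levels were measured by RNA sequencing in rosette leaves of Arabidopsis thaliana plants aged 28 days. Wild-type plants (WT) were compared with plants that expressed ERF4 from the constitutive 35S promoter of cauliflower mosaic virus (OE), with 2 libraries per genotype. ERF4 is an ethylene response factor with a repression motif, known to act on ethylene and jasmonate responses. The question was which leaf transcripts differed when ERF4 was overexpressed. Values were in TPM, transcript abundances corrected for length and scaled to the same total in every library, which keep no record of the read number, so the depth of each library is unknown. Of 33059 listed features, 23151 and 23683 had a value above 0 in WT replicates 1 and 2, and 23087 and 23340 in OE replicates 1 and 2. The labels do not say whether replicates came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

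ERF4 (AT3G15210) was measured at 10.1 ± 0.651 TPM in WT and 26.7 ± 3.09 TPM in OE (SD, n = 2), a 2.63-fold higher mean. Both OE libraries (24.5 and 28.8 TPM) lay above both WT libraries (9.68 and 10.6 TPM), in the direction of the labels. On the log2(TPM + 1) scale the difference was 1.31 (SE 0.351), which did not pass the threshold over all genes (limma, Benjamini-Hochberg adjusted p = 0.381). A gene-level TPM does not separate the transgene from the native locus. With 2 libraries per genotype an exact two-sided permutation test of one gene cannot give a p below 0.333.

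Between the genotypes, 18 of 20010 tested features passed the threshold, 12 higher and 6 lower in OE. The named transcripts that rose in OE encode BT1 and BT2, scaffold proteins with BTB and TAZ domains that are repressed by sugars, PHI-1, a protein of the EXORDIUM family, and TCH4, a xyloglucan endotransglucosylase induced by touch. UPI, a serine protease inhibitor with a role in defence, and BHLH101, a transcription factor of the iron deficiency response, also rose. The named transcripts that fell encode GASA5, a peptide of the gibberellin-regulated GASA family, and CRU3, a cruciferin stored in seeds.

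BT1 (AT5G63160) rose from 15.3 ± 4.73 TPM in WT to 248 ± 175 TPM in OE, a ratio of means of 16.3. BT2 (AT3G48360) rose from 19.7 ± 4.21 to 251 ± 30.8 TPM, 12.7-fold. PHI-1 (AT1G35140) rose from 6.04 ± 1.61 to 87.7 ± 23.7 TPM, 14.5-fold. TCH4 (AT5G57560) rose from 19.2 ± 2.06 to 274 ± 169 TPM, 14.3-fold. UPI (AT5G43580) rose from 17.615 ± 6.63 to 176 ± 68.5 TPM, 10.0-fold. BHLH101 (AT5G04150) rose from 23.8 ± 0.785 to 163 ± 19.3 TPM, 6.83-fold. GASA5 (AT3G02885) fell from 26.0 ± 0.417 to 1.01 ± 0.113 TPM, a 25.8-fold lower mean, and CRU3 (AT4G28520) from 10.04 and 25.2 TPM in the WT libraries to 0.04 and 0.21 TPM in the OE libraries, a mean of 0.125 ± 0.120 TPM (SD, n = 2 throughout). The log2 fold changes were 3.77 (SE 0.516) for BT1, 3.61 (0.389) for BT2, 3.65 (0.382) for PHI-1, 3.62 (0.476) for TCH4, 3.24 (0.436) for UPI and 2.72 (0.374) for BHLH101. They were -3.75 (0.364) for GASA5 and -3.92 (0.481) for CRU3. For BT1 the value was 4.55 without OE replicate 1 and 2.98 without OE replicate 2, and for TCH4 4.29 and 2.95. For CRU3 it was -4.54 without WT replicate 1 and -3.30 without WT replicate 2. The size for these low genes depended on the pseudocount: with 5 it was -2.37 for GASA5 and -2.06 for CRU3, which lost its call, and with 0.1 it was -4.56 and -6.26. The limma adjusted p (Benjamini-Hochberg) was 0.0221 for BT1, 0.00625 for BT2, 0.00572 for PHI-1, 0.0219 for TCH4, 0.0219 for UPI, 0.0221 for BHLH101, 0.00341 for GASA5 and 0.0182 for CRU3.

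**Figure D1:**
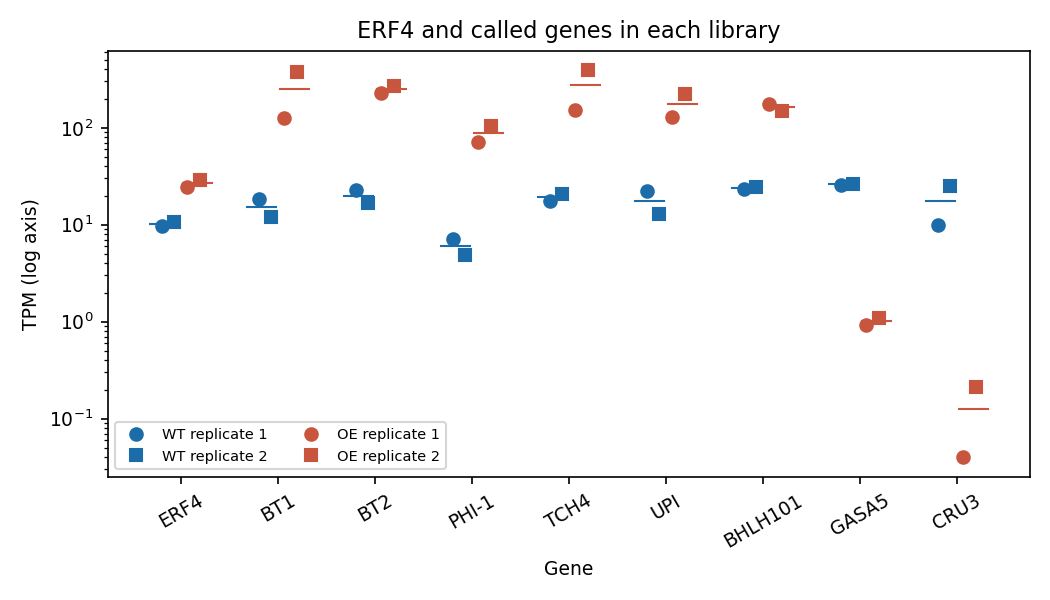
TPM of ERF4 and 8 named genes past the threshold in each of the 4 libraries, on a log axis; circles are replicate 1 and squares replicate 2, WT in blue and OE in red, and short lines are group means. Both OE libraries lie above both WT libraries for the first 7 genes and below them for GASA5 (1.01 against 26.0 TPM) and CRU3 (0.04 and 0.21 against 10.04 and 25.2 TPM).

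The small nuclear RNA U2.3 (AT3G09005), a spliceosomal RNA, was listed at 0 in both WT libraries and at 7.28 and 39.3 TPM in the OE libraries (limma, Benjamini-Hochberg adjusted p = 0.0472). Its call was lost with a pseudocount of 5, with a robust variance prior and with no variance trend, besides the fits that gave no call at all. U2 genes have near-identical copies, so the assignment of reads to this one is uncertain. Another U2 gene, U2.14 (AT1G05057), was also called but fell short of the mean of 5 TPM needed to be named by rule. Chosen for mention after its values were seen, it was listed at 0 in both WT libraries. It had 9.19 and 9.82 TPM in the OE libraries (limma, Benjamini-Hochberg adjusted p = 0.0183), with the same uncertainty of assignment. In all, 6 of the 18 features were listed at 0 in both libraries of one genotype, 13 were protein-coding, and 8 had no symbol and are counted but not named.

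The number of calls depended on the settings. With limma and quantile normalization, median-ratio scaling, no filter on low values, without WT replicate 1 or without WT replicate 2 there were 0 calls, while 1114, 1137, 1072, 1088 and 1707 features had an unadjusted p under 0.05. In each of these 5 fits all 18 features kept their sign, and the prior degrees of freedom were 3.08 to 3.49 in place of 8.73. With quantile normalization the log2 fold change was 3.59 for BT2, 2.69 for BHLH101 and -3.82 for CRU3. In the comparison as designed 1061 features had an unadjusted p under 0.05, beside 1000 expected by chance.

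Some further transcripts had small p-values and did not pass the threshold. Among those higher in OE, EXO, a growth regulator related to PHI-1, had 95.9 ± 53.0 TPM in WT and 677 ± 168 TPM in OE, and MIOX2, a myo-inositol oxygenase, 22.7 ± 13.8 and 262 ± 211 TPM. WRKY22, a transcription factor of defence and senescence, had 9.31 ± 3.18 and 40.1 ± 1.60 TPM, GDPD2, a glycerophosphodiester phosphodiesterase, 15.1 ± 6.82 and 68.3 ± 15.4 TPM, and TPS11, a protein of the trehalose phosphate synthase family, 26.6 ± 6.32 and 106 ± 7.86 TPM. Among those lower in OE, the cruciferin CRA1 had 22.1 ± 10.5 TPM in WT and 1.56 ± 1.73 TPM in OE, the chlorophyllase CLH1 31.6 ± 4.70 and 6.21 ± 1.87 TPM, and ICL, the isocitrate lyase of the glyoxylate cycle, 100.5 ± 74.5 and 8.06 ± 6.35 TPM. FMO GS-OX3, which oxygenates aliphatic glucosinolates, had 24.1 ± 21.2 and 1.59 ± 0.665 TPM, and NAS3, a nicotianamine synthase, 9.23 ± 3.49 and 0.82 ± 1.05 TPM. The limma adjusted p (Benjamini-Hochberg) of these 10 genes lay between 0.0628 for CRA1 and 0.150 for NAS3. When only features of at least 5 TPM on average were tested, all but NAS3 were called. Their limma adjusted p then ran from 0.00276 for ICL to 0.0339 for TPS11. NAS3 was called with a robust variance prior (limma adjusted p = 0.00450).

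CAT3 (AT1G20620), a catalase, and PDF1.2 (AT5G44420), a plant defensin induced by jasmonate and ethylene, were chosen for report whatever their value. CAT3 had 564 ± 547 TPM in WT and 350 ± 162 TPM in OE, a difference smaller than the spread within WT (log2 fold change -0.31, SE 0.729, limma, Benjamini-Hochberg adjusted p = 1.0). PDF1.2 had 0.62 and 5.66 TPM in the WT libraries and was listed at 0 in both OE libraries (limma, Benjamini-Hochberg adjusted p = 0.748).

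In groups of genes fixed before the data were examined, transcripts of aliphatic glucosinolate biosynthesis, jasmonate biosynthesis and signalling, flavonoid and anthocyanin biosynthesis and indole glucosinolate biosynthesis stood lower in OE. Groups for carbon and nitrogen starvation, the early response to touch, wounding and elicitors, ethylene biosynthesis and signalling, iron homeostasis and leaf senescence stood higher. These 9 of 31 lists passed camera with a preset correlation of 0.01. None of them passed with an estimated correlation, where each had an adjusted p of 0.919, and none passed with fry, so the calls rest on the assumption of a small correlation between genes of a list. The power of these checks with 2 residual degrees of freedom was not measured, so failing them neither supports nor refutes a list. The mean of the list for nuclear photosynthesis genes was 0.70 without WT replicate 1 and -0.96 without WT replicate 2. Genes of that list thus moved together between libraries, which goes against a small correlation there.

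Aliphatic glucosinolates are sulfur-containing defence compounds made from methionine. The mean log2 fold change of the 13 tested members was -1.85 (camera adjusted p = 4.38e-18, and p = 0.0919, adjusted p = 0.919, with an estimated correlation). Of these, 12 had both OE libraries below both WT libraries. The chance of that order is 1 in 6 for a single gene, and members of a pathway are not independent of each other. The list mean of log2(TPM + 1) was 6.45 and 5.45 in WT replicates 1 and 2. It was 4.64 and 3.57 in OE replicates 1 and 2, so libraries also differed within each genotype. Over all genes tested 0 members were called, and 12 fell when adjusted over the list alone. FMO GS-OX1, which oxygenates the side chain, had 18.225 ± 12.1 TPM in WT and 2.31 ± 1.28 TPM in OE, and the sulfotransferase SOT17 58.3 ± 17.1 and 14.5 ± 6.09 TPM. Further members, chosen after their values were seen, were MYB28, a master regulator of the pathway, at 54.7 and 32.4 TPM in the WT libraries and 22.0 and 17.0 TPM in the OE libraries, and MAM1, which elongates the side chain, at 265 and 128 against 70.8 and 46.9 TPM. CYP79F1 and CYP79F2 are neighbouring close paralogs, and reads shared between them make their separate values uncertain. Within the other list of this kind, for indole glucosinolates made from tryptophan, the mean over 8 members was -0.41 and the median -0.67 (camera adjusted p = 0.0433, and p = 0.123, adjusted p = 0.919, with an estimated correlation). Adjusted over the list alone 2 members fell, and over all genes 0. These were UGT74B1, a glucosyltransferase that serves both glucosinolate classes, with 114 ± 0.233 and 40.3 ± 6.02 TPM, and CYP83B1, with 125 ± 9.53 and 50.9 ± 8.83 TPM. The indole list lost its call without WT replicate 1 (adjusted p = 0.197), without WT replicate 2 (0.0961) and without OE replicate 1 (0.410), and also with median-ratio scaling (0.0813) and with a pseudocount of 0.1 (0.0714). The mean of the aliphatic list was -1.35 without WT replicate 1 and -1.31 without OE replicate 2, and its call held in each fit that left out 1 library.

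Iron homeostasis genes moved both ways. The list holds genes of the iron deficiency response and genes of iron storage, so its mean averages over unlike members. Of 17 tested members 1, BHLH101, rose over all genes, and 5 rose and 2 fell when adjusted over the list alone, with a mean of 0.52 (camera adjusted p = 0.00483, and p = 0.223, adjusted p = 0.919, with an estimated correlation). The other members that rose over the list alone, chosen for mention after their values were seen, were its relatives bHLH38 (45.4 and 47.9 TPM in WT, 293 and 122 TPM in OE), BHLH100 (51.6 and 47.5 against 438 and 99.4 TPM) and bHLH39 (44.3 and 56.6 against 310 and 86.3 TPM), and BTS, an E3 ligase that restrains the iron deficiency response (57.0 and 58.2 against 182 and 107 TPM). Those that fell over the list alone were the iron storage ferritins FER1 (69.0 and 57.6 against 19.6 and 25.8 TPM) and FER4 (30.3 and 18.5 against 12.2 and 6.6 TPM). The call of the list was lost without WT replicate 2 (mean 0.38, adjusted p = 0.998) and without OE replicate 1 (mean 0.22, adjusted p = 0.180), and the mean was 0.83 without OE replicate 2.

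**Figure D2:**
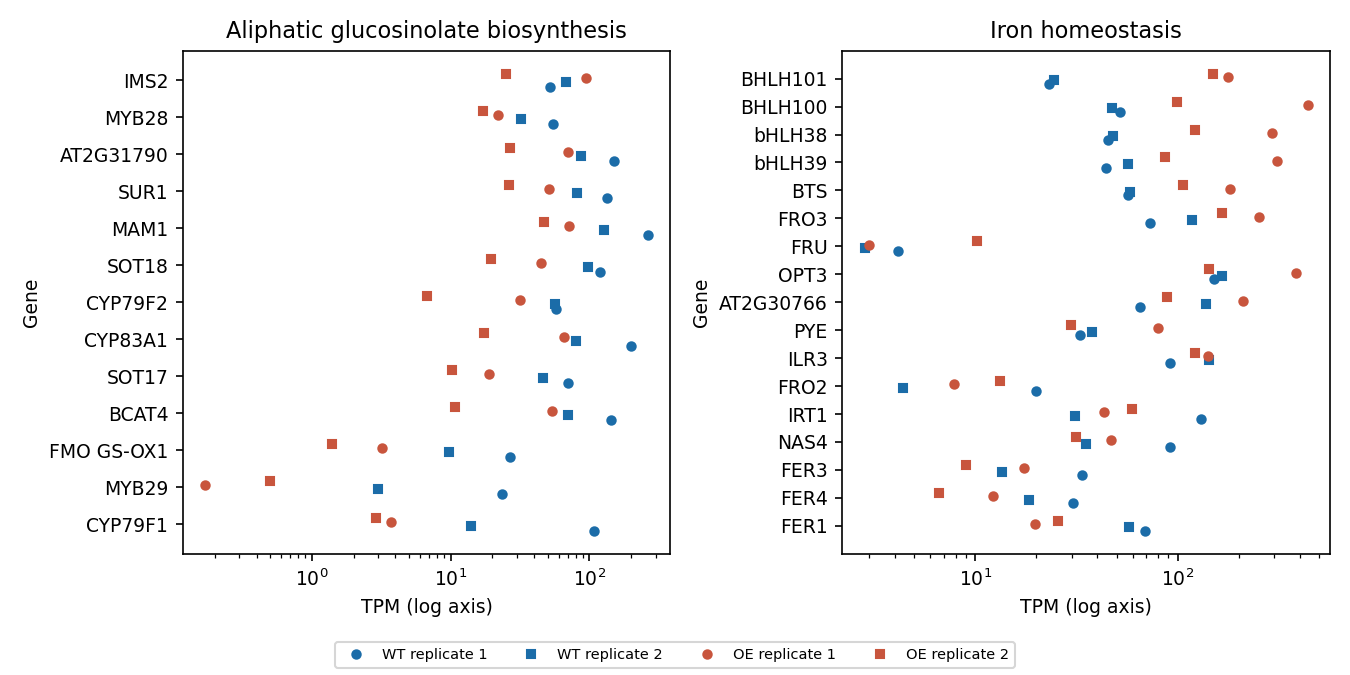
TPM on a log axis for each tested member of the aliphatic glucosinolate list (left) and the iron list (right) in each library; WT in blue and OE in red, circles for replicate 1 and squares for replicate 2. On the left 12 of 13 genes have both OE libraries below both WT libraries, and on the right 6 of 17 genes have both OE libraries above and 2 have both below.

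The carbon and nitrogen starvation list, which holds genes induced by shortage and also the nitrate reductases NIA1 and NIA2, had a mean log2 fold change of 1.33 over 10 members (camera adjusted p = 0.000105, and p = 0.221, adjusted p = 0.919, with an estimated correlation). Over all genes 0 members were called and 3 rose when adjusted over the list alone. DIN10, a raffinose synthase-like protein induced in darkness, had 142 ± 109 TPM in WT and 710 ± 229 TPM in OE, and NIA1, which nitrate itself induces, 160 ± 57.6 and 526 ± 128 TPM. The other was ASN1, the dark-induced asparagine synthetase, chosen for mention after its values were seen, at 0.38 and 42.99 TPM in WT and 49.06 and 398 TPM in OE. WT replicate 1 stood apart in this list, with a mean log2(TPM + 1) of 3.36 beside 5.38 in WT replicate 2 and 5.54 and 5.87 in the OE libraries. Without it the mean log2 fold change was 0.32 and the call was lost (adjusted p = 0.0976). Without WT replicate 2 the mean was 2.34.

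The leaf senescence list had a mean of 0.56 and a median of 0.27 over 25 members (camera adjusted p = 0.00511, and p = 0.478, adjusted p = 0.919, with an estimated correlation). Over all genes 0 were called, and 3 rose and 1 fell when adjusted over the list alone. WRKY22 was among the 3, and NYC1, a chlorophyll b reductase of chlorophyll breakdown, was the member that fell, with 47.3 ± 13.3 TPM in WT and 14.7 ± 2.34 TPM in OE. WT replicate 1 was again lower, with a list mean of 3.503 beside 5.10, 4.81 and 4.91 in WT replicate 2 and the OE libraries. Without it the mean turned to -0.24 (adjusted p = 0.962), and without WT replicate 2 it was 1.36.

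Ethylene biosynthesis and signalling genes had a mean of 0.54 over 19 members, of which 17 had a positive log2 fold change (camera adjusted p = 0.000178, and p = 0.299, adjusted p = 0.919, with an estimated correlation). The members that rose when adjusted over the list alone were 2 ACC synthases, enzymes that make the ethylene precursor. ACS7 had 4.22 ± 1.84 TPM in WT and 19.9 ± 6.60 TPM in OE, and ACS11 1.37 ± 0.339 and 7.35 ± 2.91 TPM. Over all genes 0 members were called. WT replicate 1 had the lowest list mean, 4.39 beside 5.34, 5.45 and 5.38, and without it the mean was 0.070 and the call was lost (adjusted p = 0.526), while without WT replicate 2 the mean was 1.02.

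In the early response to touch, wounding and elicitors the mean was 0.73 over 13 members (camera adjusted p = 0.000105, and p = 0.0586, adjusted p = 0.919, with an estimated correlation). TCH4 rose over all genes, and 4 members rose when adjusted over the list alone. The call held in each fit that left out 1 library. TCH4 also belongs to the expansins and xyloglucan endotransglucosylases, where 3 members rose and 4 fell when adjusted over the list alone and the list itself did not pass (mean 0.29, camera adjusted p = 0.701).

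**Figure D3:**
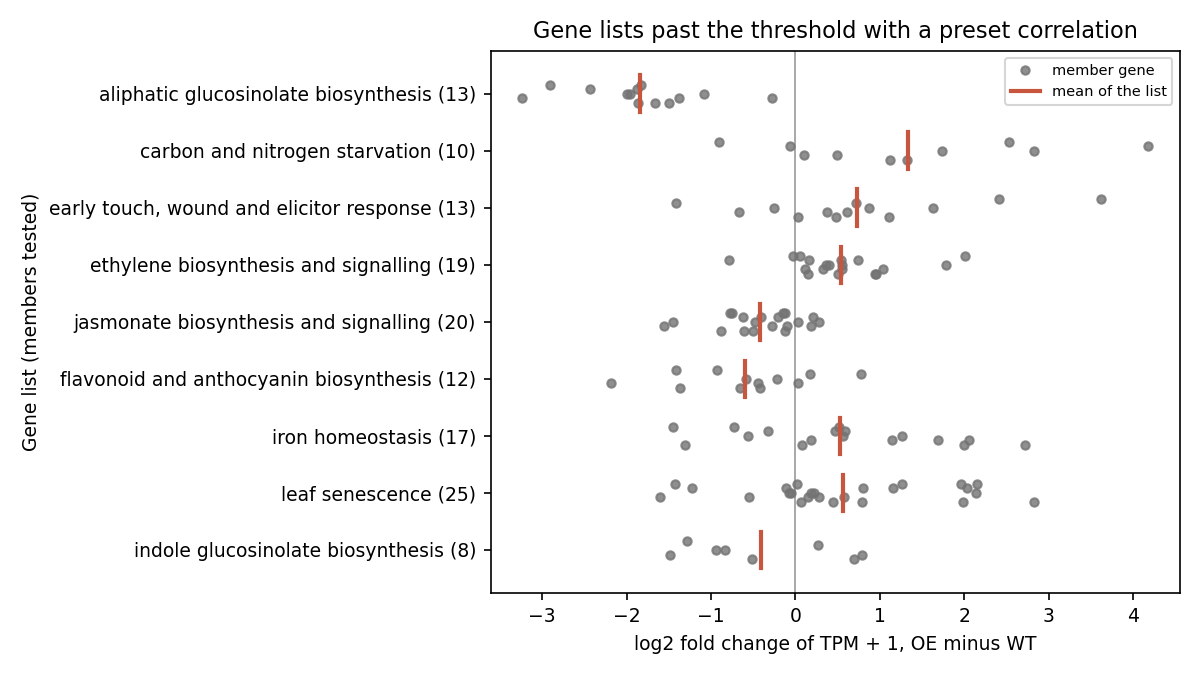
Log2 fold change (OE minus WT, on the log2(TPM + 1) scale) of each tested member of the 9 lists past the threshold with a preset correlation; grey points are genes, red bars are list means, and numbers in brackets are the members tested. The mean is -1.85 for aliphatic glucosinolates and 1.33 for carbon and nitrogen starvation, and single members of most lists lie on both sides of 0; none of the 9 passes with an estimated correlation (adjusted p = 0.919).

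Jasmonate biosynthesis and signalling had a mean of -0.42 over 20 members, 16 of them negative (camera adjusted p = 0.00187, and p = 0.199, adjusted p = 0.919, with an estimated correlation). No member was called, over all genes or adjusted over the list alone. LOX3, a lipoxygenase of jasmonate synthesis, had 4.12 ± 0.0636 TPM in WT and 0.74 ± 0.0424 TPM in OE, and the storage protein VSP2, a jasmonate-induced marker, 3.04 ± 0.785 and 0.53 ± 0.636 TPM. The mean was -0.65 without WT replicate 1 and -0.18 without WT replicate 2, and the call was lost without OE replicate 1 (mean -0.33, adjusted p = 0.172). Flavonoid and anthocyanin genes had a mean of -0.60 over 12 members (camera adjusted p = 0.00329, and p = 0.376, adjusted p = 0.919, with an estimated correlation). DFR, dihydroflavonol reductase, fell when adjusted over the list alone, with 5.35 ± 1.78 TPM in WT and 0.385 ± 0.332 TPM in OE, and 0 members were called over all genes. AT4G14090, the other gene named by rule, had 3.36 ± 0.453 and 0.635 ± 0.191 TPM. This list lost its call without WT replicate 1 (mean -0.063, adjusted p = 0.804), without OE replicate 2 (mean 0.00083, adjusted p = 0.905) and when only features of at least 5 TPM on average were tested (mean -0.33, adjusted p = 0.289). Its mean was -1.14 without WT replicate 2 and -1.21 without OE replicate 1.

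The other defence and hormone lists did not pass with all 4 libraries. The jasmonate and ethylene defence outputs had a mean of -0.58 (camera adjusted p = 0.0817), with the defensin LCR67 at 3.44 ± 2.55 TPM in WT and 0.52 ± 0.735 TPM in OE. This list was called lower without WT replicate 1 (mean -1.84, adjusted p = 1.25e-05), without OE replicate 2 (-0.68, adjusted p = 0.00414) and with no filter (adjusted p = 0.0156), while its mean was 0.68 without WT replicate 2. The ERF transcription factors other than ERF4 had a mean of -0.049 and a median of 0.038, which differ in sign (camera adjusted p = 0.978), with AT5G51190 at 7.75 ± 0.346 and 3.11 ± 3.51 TPM and ERF-1 at 35.8 ± 4.36 and 52.3 ± 10.6 TPM. Salicylic acid and systemic resistance genes had a mean of -0.044 (adjusted p = 0.943), with PAD3, an enzyme of camalexin synthesis, at 5.05 ± 1.55 and 1.65 ± 1.63 TPM and the transporter EDS5 at 6.71 ± 1.301 and 3.75 ± 1.301 TPM. The abscisic acid and osmotic response list had a mean of 0.11 (adjusted p = 0.662), with 1 member higher and 1 lower when adjusted over the list alone: the dehydrin RAB18 had 29.4 ± 18.0 and 3.96 ± 3.85 TPM, and the NAC factor RD26 16.5 ± 6.97 and 54.2 ± 20.4 TPM. That list was called higher without OE replicate 1 (0.49, adjusted p = 0.00824) and lower without OE replicate 2 (-0.27, adjusted p = 0.0439). Auxin response genes had a mean of 0.018 (adjusted p = 0.978), with IAA14 at 15.1 ± 4.32 and 31.2 ± 7.05 TPM and SAUR15 at 12.1 ± 1.62 and 6.54 ± 2.29 TPM. Type-A cytokinin response regulators had a mean of 0.071 (adjusted p = 0.701), with ARR6 at 18.0 ± 2.12 and 31.8 ± 6.26 TPM and ARR7 at 24.0 ± 2.39 and 32.1 ± 4.16 TPM. Gibberellin and brassinosteroid genes had a mean of 0.23 (adjusted p = 0.117), with the gibberellin oxidase GA2OX6 at 6.36 ± 0.651 and 11.6 ± 0.184 TPM and the DELLA protein RGL1 at 5.67 ± 2.14 and 2.49 ± 0.502 TPM, and the list was called without OE replicate 1 (0.39, adjusted p = 0.0188) and with a mean of at least 5 TPM (0.38, adjusted p = 0.0266).

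Lists of chloroplast functions did not pass with all 4 libraries, and their calls turned on single libraries. Nuclear genes for photosynthesis had a mean of -0.13 over 26 members (camera adjusted p = 0.439), with LHCB4.3 at 13.6 ± 2.43 TPM in WT and 8.61 ± 3.29 TPM in OE and RBCS1B at 4063 ± 3008 and 2031 ± 747 TPM, a gene whose near-identical family members make its share of reads uncertain. Libraries of both genotypes differed in this list: the mean log2(TPM + 1) was 11.8 in WT replicate 1, 10.1 in WT replicate 2, 10.3 in OE replicate 1 and 11.3 in OE replicate 2. Without WT replicate 1 the mean log2 fold change was 0.70 (adjusted p = 2.15e-06) and without WT replicate 2 it was -0.96 (adjusted p = 2.70e-09). The list was also called higher without OE replicate 1 (0.37, adjusted p = 0.0355) and lower without OE replicate 2 (-0.64, adjusted p = 7.17e-07). Chlorophyll biosynthesis had a mean of -0.35 (adjusted p = 0.0792), with HEMA1, the glutamyl-tRNA reductase that starts the pathway, at 235 ± 193 and 36.8 ± 0.269 TPM, lower when adjusted over the list alone, and the transcription factor GPRI1 at 75.0 ± 13.9 and 34.0 ± 2.25 TPM. The chlorophyll list was called higher without WT replicate 1 (mean 0.19, adjusted p = 0.0125), lower without WT replicate 2 (-0.90, adjusted p = 3.04e-09) and without OE replicate 2 (-0.37, adjusted p = 0.0168), and lower with a pseudocount of 5 (adjusted p = 0.0374) and a mean of at least 5 TPM (0.0385). Genes of reactive oxygen production and removal had a mean of -0.27 (adjusted p = 0.121), and -0.57 without OE replicate 1, where the list was called (adjusted p = 0.0151). The iron superoxide dismutase FSD1 had 570 ± 107 TPM in WT and 116 ± 20.5 TPM in OE, lower when adjusted over the list alone, and the catalase CAT1 25.6 ± 13.4 and 14.2 ± 4.44 TPM.

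None of the other lists passed with all 4 libraries. The heat shock response had a mean of 0.35 (camera adjusted p = 0.241), with 1 member higher and 1 lower when adjusted over the list alone: the heat shock factor HSFA2 had 1.81 ± 0.573 TPM in WT and 9.2 ± 3.97 TPM in OE, and the small chaperone HSP18.2 8.11 ± 2.44 and 2.08 ± 1.45 TPM. That list was called higher without WT replicate 2 (0.99, adjusted p = 0.0276) and without OE replicate 1 (0.74, adjusted p = 0.0136). Phosphate starvation had a mean of -0.56 (adjusted p = 0.0817), with the galactolipid synthase MGDC at 5.06 ± 1.65 and 1.47 ± 1.66 TPM and the phosphatase PS2 at 27.0 ± 19.8 and 18.4 ± 24.6 TPM, and the list was called without OE replicate 1 (-1.40, adjusted p = 1.96e-07). The cell cycle list had a mean of -0.11 (adjusted p = 0.650), with the replication genes MCM2 at 10.5 ± 1.32 and 6.78 ± 1.18 TPM and PCNA1 at 16.8 ± 4.57 and 10.99 ± 5.98 TPM, and the list was called without WT replicate 2 (-0.28, adjusted p = 0.0242). Flowering time genes had a mean of -0.040 (adjusted p = 0.701), with the floral repressor SVP at 61.6 ± 2.90 and 37.6 ± 12.7 TPM and SPL9 at 2.83 ± 0.594 and 1.15 ± 0.170 TPM. The circadian clock list had a mean of -0.054 (adjusted p = 0.978), with PRR9 at 15.3 ± 0.403 and 6.74 ± 6.07 TPM and AT5G64170 at 57.8 ± 4.51 and 33.4 ± 8.53 TPM. The clock list holds both morning and evening genes, so opposite shifts can cancel in its mean. Of its 14 tested members 4 had both OE libraries above both WT libraries and 3 had both below.

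Markers of other cell types and organs gave no difference past the threshold with all 4 libraries. The lists were short, from 3 tested members for meristem and flower to 7 for guard cells and the stomatal lineage. Failing to pass therefore does not show an unchanged tissue composition. All 3 meristem and flower markers had a negative log2 fold change, and 2 of them had both OE libraries below both WT libraries. The means were -0.055 for guard cells and the stomatal lineage (camera adjusted p = 0.877), 0.23 for phloem (0.439), -0.051 for xylem (0.940), -0.45 for meristem and flower (0.159), 0.018 for root (0.877) and 0.15 for trichome and myrosin cells (0.699). The trichome and myrosin markers were called without OE replicate 1 (0.69, adjusted p = 0.0448) and the meristem and flower markers without OE replicate 2 (-0.67, adjusted p = 0.0403). The guard cell factor MYB60 had 53.2 ± 6.84 TPM in WT and 43.1 ± 11.2 TPM in OE and the stomatal lineage receptor TMM 7.94 ± 3.12 and 10.5 ± 4.53 TPM. In the phloem the sucrose transporter SUC2 had 31.6 ± 3.80 and 44.9 ± 16.9 TPM and SEOR1 13.96 ± 1.21 and 15.9 ± 1.57 TPM. In the xylem the protease XCP1 had 44.7 ± 2.67 and 32.7 ± 3.49 TPM and XCP2 51.4 ± 4.497 and 58.4 ± 4.54 TPM. The meristem genes KNAT1 and STM had 31.9 ± 1.73 and 3.74 ± 1.87 TPM in WT and 19.5 ± 5.11 and 1.99 ± 0.283 TPM in OE. Of the root markers the auxin transporter EIR1 had 6.95 ± 0.502 and 10.8 ± 2.97 TPM and PRP3 357 ± 170 and 222 ± 44.4 TPM. The myrosinase TGG1 had 489 ± 46.6 and 1116 ± 796 TPM and the trichome factor MYB0 2.01 ± 1.82 and 0.595 ± 0.262 TPM.

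The genotypes were not separated more than the replicates. Across genes, which are not independent replicates, the Pearson correlation of log2(TPM + 1) was 0.918 between the WT libraries and 0.942 between the OE libraries, and between genotypes it lay from 0.903 to 0.946. Some abundant transcripts, chosen after their values were seen, differed within both genotypes. The light-harvesting gene LHCB1.3 had 18396 and 5133 TPM in WT replicates 1 and 2 and 5468 and 20086 TPM in OE replicates 1 and 2. Each of the ribosomal RNA features AT3G41979 and AT2G01020 had 5763, 8623, 10002 and 477 TPM in the same order.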

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

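Of the alternatives below, the removal of ribosomal RNA features, protein-coding loci alone and features above 0 in both genotypes were chosen after the data were seen. Where a value changed, the cause was not tested unless fewer features or libraries by construction explain it. Of 1259 comparisons of named genes with an alternative, 1134 kept their direction and side of the threshold, 49 lost a call, 70 gained one and 6 changed sign. Of 587 for gene lists the numbers were 496, 31, 21 and 39. Most named genes were not called in the comparison as designed, so for them keeping their side means staying uncalled. Among the called ones, U2.3 stayed called in 7 of 15 alternatives and CRU3 in 11 of 17. BT1, BT2, PHI-1, TCH4, UPI, BHLH101 and GASA5 stayed called in 12 of 17 each. ERF4 was called in 0 of 17 alternatives, with a log2 fold change from 1.06 to 1.42 and adjusted p (limma, Benjamini-Hochberg) from 0.146 to 1. Leaving out a library leaves 1 library in an arm, which is then assumed to vary like the other genotype. Depth is unknown, so what it limits cannot be stated. No annotation term enrichment was run, nor its alternatives, because the table used here has no terms.

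Every call in these counts was at least 2-fold. Against 18 calls (12 higher, 6 lower), limma called 0 (0 higher, 0 lower) with no filter, with quantile normalization, with median-ratio scaling, without WT replicate 1 and without WT replicate 2. A mean of at least 5 TPM gave 63 (38 higher, 25 lower), a robust variance prior 108 (59 and 49), a pseudocount of 5 14 calls with 3 lower, and a pseudocount of 0.1 19 calls. Removing organelle genes gave 17 and dropping the variance trend 21. Removing ribosomal RNA features gave 27 with 10 lower, protein-coding loci 32 with 18 higher and 14 lower, and features above 0 in both genotypes 12 with 3 lower. Leaving out 1 library gave from 0 to 147 calls, from 0 to 94 higher, from 0 to 53 lower, and 0 to 147 of at least 2-fold, with 51 without OE replicate 2 and the highest without OE replicate 1. The median log2 fold change of all features was -0.016, and it shifted by over 0.1 in 2 of these fits, to -0.16 without WT replicate 1 and 0.14 without WT replicate 2. The share of higher features among those with an unadjusted p under 0.05 was 50.8%, and 31.6% and 68.1% in those 2 fits. With the replicate number as a block limma called 338 features (186 higher, 152 lower, 338 of at least 2-fold), with 1 residual degree of freedom. The labels do not state that replicate numbers pair the libraries, and the column of the second WT library carries another number. Across genes the deviations from the group means correlated at 0.0325 between the genotypes, which shows no general shared shift but cannot exclude pairing. The prior degrees of freedom of this fit were infinite, so its spread came from other genes alone, and its calls are given no weight. With the block the indole glucosinolate list lost its call, and the lists for jasmonate and ethylene defence outputs and phosphate starvation gained one.

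With an estimated correlation camera called 0 lists higher and 0 lower, and fry called 0 higher and 0 lower, against 5 and 4. Leaving out a library gave from 4 to 9 lists higher and from 3 to 8 lower. The correlation within WT, within OE and between genotypes was 0.886, 0.925 and 0.898 with a mean of at least 5 TPM, and 0.890, 0.915 and 0.897 with a pseudocount of 0.1.

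Means of lists that were not called changed sign in these alternatives: auxin to -0.037 with a pseudocount of 0.1, flowering time to 0.0093 and root markers to -0.033 with a pseudocount of 5, and guard cell markers to 0.0012 with no filter. A mean of at least 5 TPM turned the ERF list to 0.026, salicylic acid to 0.030 and root markers to -0.016. Quantile normalization turned photosynthesis to 0.010 and flowering time to 0.0075, and removal of ribosomal RNA features turned salicylic acid to 0.032.

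Leaving out a library turned the sign of these results, given from lowest to highest. Genes were CAT3 (-1.52 to 0.89), RBCS1B (-1.66 to 0.019), TMM (-0.066 to 0.76) and PS2 (-3.61 to 0.60). Lists past the threshold were leaf senescence (-0.24 to 1.36) and flavonoids (-1.21 to 0.00083). The others were photosynthesis (-0.96 to 0.70), chlorophyll (-0.90 to 0.19), heat shock (-0.28 to 0.99), cell cycle (-0.37 to 0.14), auxin (-0.22 to 0.26), ERF factors (-0.54 to 0.44), jasmonate and ethylene defence (-1.84 to 0.68), salicylic acid (-0.32 to 0.23) and abscisic acid (-0.27 to 0.49). Reactive oxygen (-0.58 to 0.038), clock (-0.23 to 0.12), flowering time (-0.39 to 0.31) and phosphate (-1.40 to 0.28) also turned, as did the markers of root (-0.12 to 0.15), xylem (-0.11 to 0.0050), guard cells (-0.22 to 0.11) and trichomes (-0.39 to 0.69).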

Other observations

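EM1 and PAP85, genes of seed maturation, were picked after their values had been seen. The late embryogenesis protein EM1 had 7.52 ± 1.00 TPM in WT and 0.265 ± 0.375 TPM in OE, and the vicilin-like storage protein PAP85 4.69 ± 0.212 and 0.27 ± 0.339 TPM (SD, n = 2). Neither passed the threshold (limma, Benjamini-Hochberg adjusted p = 0.0628 and 0.184). Among iron genes outside the list, also picked after their values were seen, NAS1, a nicotianamine synthase, had 244 and 80.7 TPM in the WT libraries and 22.2 and 29.99 TPM in the OE libraries (limma, Benjamini-Hochberg adjusted p = 0.191). The small protein genes AT1G47395 and AT1G47400 had 33.6 and 62.4, and 15.1 and 17.7 TPM in WT, and 259 and 165, and 80.8 and 30.9 TPM in OE, without passing (limma, Benjamini-Hochberg adjusted p = 0.187 and 0.454).

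All of the 5 tests below were chosen after the main results were seen. The bounds were written before the tested values were seen, except for the scaling test of CRU3, and the clock genes also belong to a list whose overall result had been seen. For 3 tests (seed material, carbon status, hour of harvest) the reading was made stricter after the value was known, and the outcome under the bound as first written is given for each. The number of further carbon genes was also first written as 1 fewer, although the list always held 16. Gene lists in the alternatives were at first compared by the direction camera gives, which counted more changes of sign, and then by the sign of the mean, which counts 39.

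CRU3 fell and CRA1 was lower in OE. If scaling between libraries were the cause, CRU3 would approach 0 after quantile normalization, and it stayed at -3.82, although limma called no gene under that setting. That test could hardly come out otherwise, since the median-ratio factors of the libraries lay only between 0.89 and 1.14. Scaling differences of that size are too small for CRU3 at 10.04 and 25.2 TPM in WT and 0.04 and 0.21 TPM in OE. Seed or embryo material in the WT samples may be another cause. Of 9 further seed genes 3 had both WT libraries above both OE libraries at a WT mean of at least 1 TPM, which meets exactly the bound of 3 or fewer that was written against this explanation, with no margin. Without the TPM minimum 5 of the 9 had that order, and 8 of the 9 had a negative log2 fold change. OLEO1, an oil body protein, was among the 3 with 4.68 TPM in WT and 0.445 TPM in OE, while the albumin SESA2 had 5.98 TPM in WT and 13.7 TPM in OE. The libraries of SESA2 overlapped, with 0.26 and 11.7 TPM in WT and 23.8 and 3.51 TPM in OE. Most of these genes lay near the floor, so seed material and an effect of the genotype cannot be told apart.

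BT1, BT2, DIN10 and ASN1 respond to low carbon, and a lower carbon status of the OE leaves is a candidate explanation. Over 16 further genes induced by low carbon the median log2 fold change was 1.27, 15 were positive, and 7 (43.75%) had both OE libraries above both WT libraries, which met the bound as written. Without WT replicate 1 the median was 0.226, below the bound, so 1 WT library decides it and the explanation stays open. A different hour of harvest was tested through morning minus evening clock genes, which differed between OE and WT by -1.09 (SE 0.592) with values of 2.51 and 2.19 in WT and 1.83 and 0.687 in OE. This met the bound as written too. The difference was -0.521 without OE replicate 2, -0.93 without WT replicate 1, -1.25 without WT replicate 2 and -1.66 without OE replicate 1. The 16 further genes had a mean log2(TPM + 1) of 6.09 in WT replicate 2 and 6.12 in OE replicate 1. BT2 had 16.8 and 229 TPM in these libraries and BT1 11.9 and 125 TPM, although the further genes were nearly level there. That compares 1 library per genotype, so carbon status, hour of harvest and genotype cannot be told apart.

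Of the 18 calls, 6 were listed at 0 in both libraries of one genotype, and uneven assignment of reads, unrelated to genotype, may be the source. Features at 0 in one pair of libraries and at 3 TPM or more in both of the other numbered 12 for WT against OE. The other 2 divisions of the 4 libraries into pairs gave 12 and 9, which met the bound written for uneven assignment. Other variation between libraries that is unrelated to genotype could give such counts too, so they do not single out assignment of reads. They also cover all features from 3 TPM, not the 6 called ones alone.

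The other 2 divisions of the libraries gave 0 calls each, against 18, and 766 and 928 features with an unadjusted p under 0.05 by limma, against 1061. There are too few divisions for a share under 0.05. Each of the other divisions also puts a WT and an OE library in the same group. Any difference between the genotypes then adds to the spread and lowers the calls, so they are not a reference without change. The mean of the aliphatic glucosinolate list was -1.85 for the genotypes and -1.04 and 0.037 for the others, and that of the photosynthesis list -0.13, -0.32 and -1.34.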
